A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

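Biotin-labelled polyA RNA from 4 yeast strains, 2 samples each, was hybridised to an Affymetrix yeast array, per the labels. RNA was extracted with acid phenol and labelled by the standard Affymetrix procedure, per the labels' protocols. The deposited values are signal intensities on a linear scale, 1 per probe set and array; the software that made them is not given in the sources used here. Their mean after trimming 2% at each end was 100.1 on all 8 arrays, so the deposited intensities had been brought to a common scale. The table held 9335 probe sets, of which 60 controls were left out. Of the 9275 others, 6504 named 1 gene in the platform annotation, 328 named several and 2443 named none; all 6504 were matched by gene identifier to current symbols of assembly R64. A probe set with several genes or none was tested and counted but not named.

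The array medians differed by 0.419 on the log2 scale, above the tolerance of 0.2, so each array was centred on its median. Signals under the 10th percentile of all values, 1.72, were set to it and log2 was taken; a change against a strain at the floor is a lower bound. A probe set was kept if its highest strain mean exceeded the 25th percentile, a signal of 6.99, which left 7509, and the probe set with the highest mean stood for each gene, which left 7043.

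Strains were compared with limma 3.58.1 in R 4.3.3: a mean per strain over all 8 arrays, 6 contrasts, moderated statistics with an intensity trend, and Benjamini-Hochberg adjustment over the 7043 probe sets at a threshold of 0.05. Nothing in the labels says whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The replicate number was left out of the fit chosen before the data were examined, and a fit with it as a block was planned beside it. The labels give the numbers but no shared day or batch. Deviations of same-numbered arrays from their strain means correlated across probe sets in all 6 strain pairs, with r from 0.188 to 0.739, and the first principal component, 47.7% of the variance, separated replicate 1 from replicate 2. The numbers were therefore taken to pair the arrays, and blocked values stand beside the others wherever a call or count changed.

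Arrays were simulated for not1-2 against wild type over 7043 probe sets with the real means and independent Gaussian noise of the fitted size. The mean replicate effect was added alike in every strain. The fit without the block recovered 0% of 100 probe sets changed by 1 and 0% of 100 changed by 2 on the log2 scale. The blocked fit recovered 11% and 85%, with 6 false calls. A simulated list shifted by 0.5 was called in both fits and 0 of 41 other lists were. In the data the replicate effect differed between strains, so these rates may not hold there. The simulated noise had no correlation between genes, so it does not test the preset correlation used for the lists.

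Of 43 gene lists fixed before the data were examined, 41 had at least 5 measured genes; the alpha-specific genes and core histones had 4 each. Of their 1290 entries 1285 matched a current symbol. Lists were tested with camera, 2-sided, at a preset correlation of 0.01, adjusted over 246 tests; the estimated correlation was the alternative, and of the 56 calls, or 60 with the block, 0 held with it. The named genes were SPT3 and CDC39, and per contrast the 6 highest and 6 lowest probe sets that passed, named 1 gene and did not overlap between the strains. Added to them were, per called list, up to 4 passing members, or else the 2 with the smallest p as values, and the a-specific, alpha-specific and marker genes as a check of the strains. Applying the same rule to the blocked fit was decided after the data were seen. HMRA1 and other genes named in the text followed from it.

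Alternatives changed 1 choice at a time: the scaling, the floor, the filter, the trend, the arrays in the fit, the threshold, the probe sets of a gene and each array left out in turn, where the lone array of a strain was assumed to vary like the others. The least-varying probe sets were taken from the brighter part of the array, a detail set after the data were seen. The filter on probe sets of another species was not run. The 3' to 5' ratio of ACT1 as a covariate, and alternatives on top of the block, were added after the data were seen.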

Results

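RNA levels were measured on 8 yeast arrays, from 4 strains of Saccharomyces cerevisiae with 2 arrays each: the wild-type reference, a strain with the not1-2 allele, a strain with the spt3 mutation and the not1-2 spt3 double mutant. Not1, encoded by CDC39, is the scaffold of the Ccr4-Not complex, and Spt3 is a subunit of the SAGA coactivator that works with the TATA-binding protein. Cells grown for 24 h at 30°C in glucose-rich medium were moved at an optical density of 0.2 to the restrictive temperature of 37.5°C and collected at 0.8. The design asks what each mutation changes alone, and whether the changes of not1-2 need a functional SPT3. The arrays carry no read depth, and 2 per strain limit the precision: 7043 probe sets were tested, of which 5355 named 1 gene, and the median standard error of a difference between strains was 0.486 on the log2 scale.

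Control signals that bear on RNA quality differed between the arrays. The 3' to 5' signal ratio of the ACT1 control was 199.1 on wild-type replicate 1, 36.8 on not1-2 replicate 1, 5.83 on spt3 replicate 1 and 12.2 on not1-2 spt3 replicate 1, against 1.88, 2.10, 1.79 and 1.84 on the replicate 2 arrays. The SPT15 control gave ratios of 72.5, 25.1, 12.2 and 19.3 on the replicate 1 arrays and between 3.44 and 5.30 on the others. The spike-in controls averaged a signal of 725.4 on wild-type replicate 1 and 265.6 on replicate 2. Replicates correlated across probe sets with r = 0.864 in wild type, 0.913 in not1-2, 0.95 in spt3 and 0.92 in the double mutant.

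**Figure D1:**
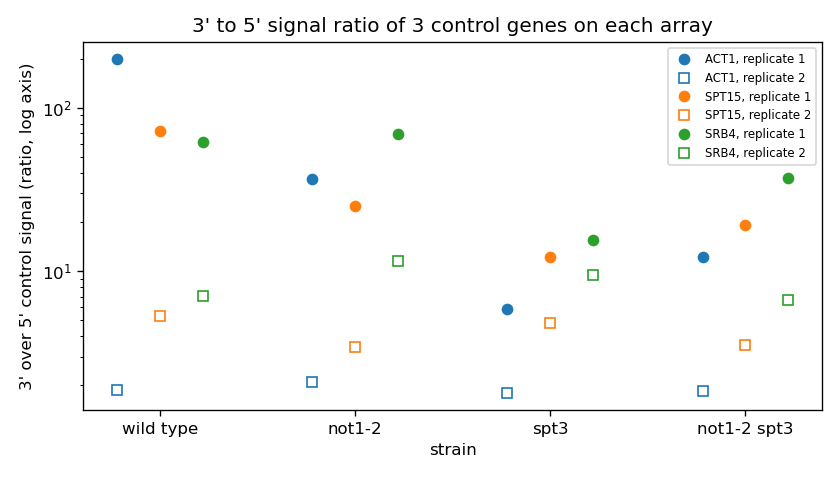
Ratio of the 3' to the 5' control signal (vertical log axis, no unit) for ACT1, SPT15 and SRB4 on each of the 8 arrays, by strain on the horizontal axis; filled circles are replicate 1 and open squares replicate 2. Each gene's ratio was higher on replicate 1 in every strain, and ACT1 ran from 5.83 to 199.1 on replicate 1 and from 1.79 to 2.10 on replicate 2.

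The mutated genes and the strain markers came first. SPT3 gave signals of 25.3 and 15.5 in wild type and 29.9 and 22.8 in not1-2, and was at the floor of 1.72 on all 4 arrays of the strains labelled spt3, at least 11.5-fold below wild type. That difference had an adjusted p of 0.112, and 0.0206 with the replicate number as a block. TRP1, a tryptophan synthesis gene often used as a marker, was at the floor on all 4 arrays of wild type and not1-2. It rose by 4.87 ± 0.43 (SE, log2, 2 against 2 arrays) in spt3 and by 4.65 ± 0.43 in the double mutant, at adjusted p of 0.0152 and 0.0212. A comparison of spt3 or the double mutant with wild type or not1-2 therefore also sets strains of unlike TRP1 expression against each other. CDC39 differed from wild type by -0.06 in not1-2, 1.09 in spt3 and 0.92 in the double mutant, at adjusted p of 0.991, 0.864 and 0.959. What the not1-2 allele alters is not given in the sources used here, so the level of CDC39 checks no label.

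Genes of mating type separated wild type from all 3 mutants. MFA2, which encodes the a-factor pheromone, gave signals of 4970 and 1450 in wild type and between 7.44 and 18.0 in the mutants. MF(ALPHA)1, which encodes the alpha-factor, gave 14.9 and 17.1 in wild type and between 534 and 1620 in the mutants. Of the 7 a-specific genes, all 7 lay below wild type in each mutant, with list medians of -3.70 in not1-2, -4.61 in spt3 and -4.01 in the double mutant and camera adjusted p of 2.33e-13, 4.74e-17 and 1.24e-18. With an estimated correlation the adjusted p was 0.0772 in each case. Every difference from wild type given below therefore also sets strains of unlike mating-type expression against each other. Between the mutants these genes differed less, though MFA1 was lower in the double mutant than in not1-2 by -2.16 (adjusted p = 0.719, and 0.0316 with the block).

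**Figure D2:**
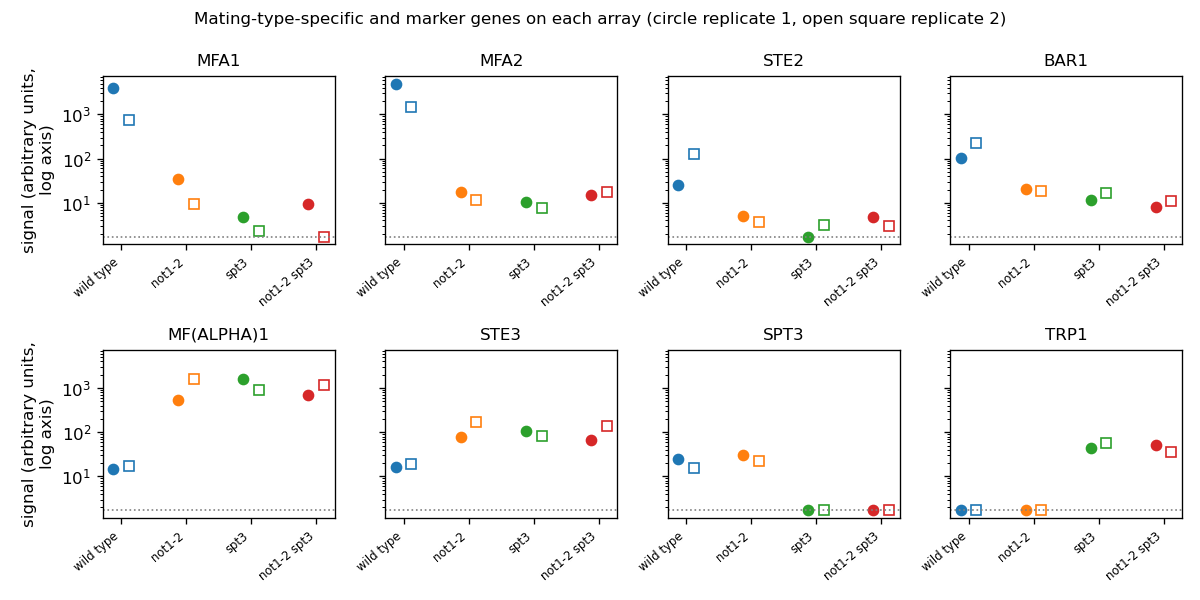
Signal (vertical log axis, arbitrary units) of a-specific genes (MFA1, MFA2, STE2, BAR1), alpha-specific genes (MF(ALPHA)1, STE3), SPT3 and TRP1 on each of the 8 arrays, by strain; circles are replicate 1, open squares replicate 2 and the dotted line is the floor of 1.72. SPT3 was at the floor in spt3 and not1-2 spt3, and MFA2 fell from at least 1450 in wild type to at most 18.0 in the mutants.

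The comparison of not1-2 with wild type asks what the NOT1 mutation changes while SPT3 is intact. With the replicate block, 73 probe sets were higher and 67 lower in not1-2. Among probe sets that named 1 gene, outside the mating-type genes, the 5 highest estimates were those of JLP1, a sulfonate dioxygenase (4.40 ± 0.58, blocked SE, adjusted p = 0.012), the flocculin gene FLO1 (4.31 ± 0.55, adjusted p = 0.00968) and the cell wall protein gene PIR3 (4.21 ± 0.57, adjusted p = 0.0123). The others were MPC3, a subunit of the mitochondrial pyruvate carrier (4.20 ± 0.52, adjusted p = 0.00968), and SPG4, a stationary-phase gene (3.83 ± 0.35, adjusted p = 0.00288). JLP1 was at the floor on both wild-type arrays and FLO1 and MPC3 on 1 each, so their rises are lower bounds and the 5 have no order. The lowest that named 1 gene, beside HMRA1 and the a-specific MFA2, MFA1 and AGA2, were the tRNA gene SUF10 (-4.43 ± 0.92, adjusted p = 0.0482) and the mitochondrial cytochrome b gene COB (-3.79 ± 0.61, adjusted p = 0.0235, a bound, with both not1-2 arrays at the floor). SUF10 lay below wild type in all 3 mutants. Its log2 means were 7.87 in wild type, 3.44 in not1-2, 3.74 in spt3 and 5.08 in the double mutant, and its probe set may match related sequences. Without the block only MF(ALPHA)1 was higher and only MFA2 and HMRA1 were lower, at adjusted p of 0.029, 0.0109 and 0.029, and 540 probe sets had an unadjusted p under 0.05.

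Stress, storage and cell wall genes were higher in not1-2. Of the 45 targets of the stress factors Msn2 and Msn4, 34 lay above wild type, with a list median of 0.72 (adjusted p = 1.5e-08, and adjusted p = 0.51 with an estimated correlation). With the block 6 passed, among them HSP12 (3.26 ± 0.49), CRG1 (2.91 ± 0.52), TMA10 (2.35 ± 0.30) and DDR2 (2.16 ± 0.29). No member passed without the block over all probe sets, and 5 did adjusted over the list alone. Of the 22 cell wall integrity genes 21 lay above wild type, with a median of 0.85 (adjusted p = 6.7e-08, and adjusted p = 0.759 with an estimated correlation). PIR3, YPS3 (1.62 ± 0.33) and PST1 (1.54 ± 0.26) passed with the block, and 4 adjusted over the list alone. Of the 20 trehalose and glycogen genes 17 lay above, with a median of 0.58 (adjusted p = 0.000647, and adjusted p = 0.759 with an estimated correlation), and the glycogen phosphorylase gene GPH1 passed with the block (1.88 ± 0.32).

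Phosphate and carbon-source genes moved the same way. Of 16 phosphate regulon genes 14 lay above wild type, with a median of 0.69 (adjusted p = 7.33e-05, and adjusted p = 0.794 with an estimated correlation). The transporter gene PHO89 (2.19 ± 0.41) and the acid phosphatase gene PHO5 (1.87 ± 0.38) passed with the block. Of 17 gluconeogenesis and glucose-repressed genes 13 lay above, with a median of 0.24 (adjusted p = 0.00503, and adjusted p = 0.794 with an estimated correlation). The lactate permease gene JEN1 (2.48 ± 0.51) and PCK1, the gluconeogenic carboxykinase (1.54 ± 0.32), passed with the block. The tricarboxylic acid and glyoxylate list had a median of 0.32 (adjusted p = 0.00731, and adjusted p = 0.807 with an estimated correlation), with malate synthase MLS1 at 2.61 ± 0.53. The lists of the respiratory chain (median 0.33), peroxisome (0.36) and mitochondrial ribosomal proteins (0.16) also passed, at adjusted p of 0.00178, 0.0208 and 0.0384, and adjusted p = 0.875, 0.835 and 0.875 with an estimated correlation. On the replicate 1 and 2 arrays the respiratory chain was at 0.14 and 0.45 and mitochondrial ribosomal proteins at 0.22 and 0.04. ECI1, a peroxisomal isomerase, passed with the block (1.53 ± 0.30).

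Growth genes lay lower in not1-2. Of 89 ribosome biogenesis genes 25 lay above wild type, with a median of -0.29 (adjusted p = 0.00526, and adjusted p = 0.875 with an estimated correlation), and of -0.44 and -0.14 in the replicate pairs. DBP2 (-1.79 ± 0.30) and GAR1 (-1.18 ± 0.24) passed with the block. Cytosolic ribosomal proteins had a median of -0.36 over 80 genes (adjusted p = 0.0384, and adjusted p = 0.958 with an estimated correlation). Their median was -0.60 on the replicate 1 arrays and -0.18 on the replicate 2 arrays, and it became 0.04 after quantile normalization, with no call. The wild-type and not1-2 replicate 1 arrays had the highest ACT1 ratios, 199.1 and 36.8. With the ACT1 ratio as a covariate on top of the block 21 of the 33 named genes called in not1-2 still passed. The 12 others, HSP12, CRG1, JEN1, PHO5, PHO89, MLS1, ECI1, YPS3, GAR1, COB and SUF10 among them, kept between 86.9% and 107% of their log2 change, at adjusted p of at most 0.118, in a fit with fewer residual degrees of freedom. The blocked count of 140 fell to 4 without wild-type replicate 1, 6 without wild-type replicate 2, 3 without not1-2 replicate 1 and 2 without not1-2 replicate 2. It was 92 and 77 without a double-mutant array and 306 and 291 without an spt3 array. Other scalings raised the share of higher probe sets among blocked calls from 52.1% to 65.7% (quantile), 72% (no centring) and 65.9% (least-varying probe sets).

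The comparison of spt3 with wild type asks what loss of SPT3 changes while NOT1 is intact. Beside TRP1 and the mating-type genes, the serine synthesis gene SER3 rose by 3.13 ± 0.31 (blocked SE, adjusted p = 0.00325). AFB1 (2.68 ± 0.41, adjusted p = 0.0367), PLN1 (2.56 ± 0.44, adjusted p = 0.0489) and YDR034C-A (2.51 ± 0.41, adjusted p = 0.0474) also rose. AFB1, the a-factor barrier gene of alpha cells, is in no fixed list. AFB1 and PLN1 set wild type apart from all 3 mutants: they also passed as higher in not1-2 with the block, by 3.18 and 2.48, and lay 2.45 and 2.49 above wild type in the double mutant (blocked adjusted p = 0.055 and 0.065). The cell wall mannoprotein genes DAN1 (-4.39 ± 0.66) and TIR3 (-2.58 ± 0.40), which yeast uses without oxygen, fell at adjusted p = 0.0367 each. In all, 12 probe sets were higher and 28 lower with the block. With the ACT1 ratio in addition 0 were higher and 2, MFA1 and MFA2, lower. SER3 was then at 2.73 ± 0.37 (adjusted p = 0.107), AFB1 at 2.14 ± 0.51 (adjusted p = 0.518), PLN1 at 2.49 ± 0.64 (adjusted p = 0.551), YDR034C-A at 1.85 ± 0.48 (adjusted p = 0.551), DAN1 at -4.58 ± 0.99 (adjusted p = 0.476) and TIR3 at -2.31 ± 0.55 (adjusted p = 0.518), none past the test, with larger SEs and fewer residual degrees of freedom. With quantile normalization on top of the block 4 were higher and 9 lower, and PLN1, YDR034C-A, DAN1 and TIR3 were at adjusted p between 0.0545 and 0.0601. Without the block MF(ALPHA)1 and TRP1 were higher and MFA2 and HMRA1 lower, and 388 probe sets had an unadjusted p under 0.05.

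Of 16 anaerobic mannoprotein genes 15 lay at or below wild type in spt3, with a list median of -1.17, and -1.19 and -1.26 in the replicate pairs (adjusted p = 6.7e-08, and adjusted p = 0.794 with an estimated correlation). DAN1 and TIR3 passed with the block, and 4 genes adjusted over the list alone. The Msn2 and Msn4 targets had a median of 0.53, with 34 of 45 above wild type (adjusted p = 1.81e-05, and adjusted p = 0.759 with an estimated correlation). The respiratory chain had a median of 0.67 with 36 of 40 above (adjusted p = 3.61e-08, and adjusted p = 0.794 with an estimated correlation), and was at 0.98 and 0.37 on the replicate 1 and 2 arrays. No member of either list passed in either fit; HSP12 was at 2.23 ± 0.54 and QCR2, a subunit of the cytochrome bc1 complex, at 1.66 ± 0.63. Heat shock genes (median 0.44), the proteasome (0.35) and mitochondrial ribosomal proteins (0.40) passed as lists at adjusted p of 0.000334, 0.000444 and 1.81e-05, and adjusted p = 0.794, 0.835 and 0.824 with an estimated correlation. On the replicate 2 arrays, where the ACT1 ratios were 1.79 and 1.88, these medians were 0.09, 0.06 and 0.06, against 0.89, 0.62 and 0.66 on the replicate 1 arrays.

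Smaller shifts in spt3 were those of ribosome biogenesis (median 0.16, adjusted p = 0.0377), the tricarboxylic acid list (0.30, adjusted p = 0.0438), amino acid synthesis under Gcn4 (0.18, adjusted p = 0.00587), which holds SER3, and subtelomeric genes (-0.48, adjusted p = 0.0288). With an estimated correlation their adjusted p was 0.875, 0.846, 0.875 and 0.835, and the subtelomeric call was lost with the block, at adjusted p = 0.068. On the replicate 1 and 2 arrays ribosome biogenesis was at 0.24 and 0.08, the tricarboxylic acid list at 0.69 and -0.03 and amino acid synthesis at 0.43 and -0.03. The blocked count of 40 became 5 without wild-type replicate 1, 9 without wild-type replicate 2, 10 and 9 without a not1-2 array, 8 without spt3 replicate 1, 630 without spt3 replicate 2, and 20 and 17 without a double-mutant array.

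The double mutant against wild type gave 3 probe sets higher and 11 lower with the block, and 2 higher and 3 lower without it, with 303 at an unadjusted p under 0.05. SER3 rose by 3.12 ± 0.31 (blocked SE, adjusted p = 0.00378), a value close to the 3.13 in spt3, and YNL146C-A fell to the floor, by at least 4.58 on the log2 scale (adjusted p = 0.0185). YNL146C-A lay below wild type in all 3 mutants, by -3.02 in not1-2 and -4.26 in spt3 (blocked adjusted p = 0.0416 and 0.0307). With the ACT1 ratio on top of the block SER3 was at 2.81 ± 0.34 (adjusted p = 0.0583) and YNL146C-A at adjusted p = 0.208, with fewer residual degrees of freedom. BAR1, which encodes the protease that degrades alpha-factor, fell by 4.01 in the fit without the block (adjusted p = 0.0403). The anaerobic mannoproteins had a median of -1.17 (adjusted p = 6.1e-07, and adjusted p = 0.794 with an estimated correlation) with no member past the test; DAN1 was at -3.90 ± 0.73 and DAN4 at -1.75 ± 0.35.

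The Msn2 and Msn4 targets were at a median of 0.53 in the double mutant (adjusted p = 2.07e-06, and adjusted p = 0.653 with an estimated correlation). The respiratory chain (0.48), mitochondrial ribosomal proteins (0.40), proteasome (0.34) and heat shock genes (0.50) passed at adjusted p of 2.91e-07, 1.3e-07, 0.000168 and 0.000137, and adjusted p = 0.794, 0.794, 0.824 and 0.794 with an estimated correlation. Heat shock genes were at 0.84 on the replicate 1 arrays and 0.06 on the replicate 2 arrays. Trehalose and glycogen genes (0.36, adjusted p = 0.0358) and the tricarboxylic acid list (0.23, adjusted p = 0.0363) had adjusted p of 0.794 and 0.835 with an estimated correlation. Cytosolic ribosomal proteins (-0.24) were called with the block, at adjusted p = 0.0169 (and adjusted p = 0.914 with an estimated correlation), and not without it, at adjusted p = 0.704; they were at -0.43 and -0.09 on the replicate 1 and 2 arrays. The blocked count of 14 became 4 without wild-type replicate 1, 8 without wild-type replicate 2, 9 without either not1-2 array, 133 and 130 without an spt3 array and 9 without double-mutant replicate 2.

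Set against not1-2, the double mutant shows what differs with loss of SPT3 once NOT1 is mutated, with no wild-type array in the comparison. TRP1 expression differs between these strains too. With the block 146 probe sets were lower and 20 higher. The lowest that named 1 gene were FLO1 (-4.52 ± 0.55, adjusted p = 0.00876), HTC1 (-4.45 ± 0.35, adjusted p = 0.00261) and CPP3 (-4.34 ± 0.38, adjusted p = 0.00261). With them were SHH3 (-4.20 ± 0.70, adjusted p = 0.0276), SPT3 itself (-3.93 ± 0.45, adjusted p = 0.00772) and JEN1 (-3.89 ± 0.51, adjusted p = 0.0114). FLO1, SHH3 and JEN1 were at the floor on 1 double-mutant array and SPT3 on both, so these are lower bounds in size and the genes have no order. TRP1 (4.65), YDR034C-A (3.15 ± 0.41), YJL047C-A (2.31 ± 0.30), the small nucleolar RNA gene SNR41 (2.22 ± 0.45), SER3 (2.16 ± 0.31) and YAR068W (2.12 ± 0.34) were the highest that passed and named 1 gene, at adjusted p between 0.00261 and 0.0458. Without the block TRP1 was higher and HTC1 lower, both at adjusted p = 0.0212, and 536 probe sets had an unadjusted p under 0.05.

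Several of the groups that were higher in not1-2 were lower once SPT3 was missing; both differences use the same not1-2 arrays. Of 17 gluconeogenesis and glucose-repressed genes 4 lay above not1-2, with a median of -0.68 (adjusted p = 0.000373, and adjusted p = 0.759 with an estimated correlation), and JEN1 and PCK1 (-1.93 ± 0.32) passed with the block. Of 16 phosphate regulon genes 3 lay above, with a median of -0.55 (adjusted p = 0.000236, and adjusted p = 0.794 with an estimated correlation), and SPL2 (-3.34 ± 0.64), PHO89 (-2.43 ± 0.41) and PHO5 (-2.25 ± 0.38) passed with the block. Of 22 cell wall integrity genes 3 lay above, with a median of -0.41 (adjusted p = 0.000513, and adjusted p = 0.794 with an estimated correlation), and the yapsin gene YPS3 (-2.83 ± 0.33) and PST1 (-2.01 ± 0.26) passed with the block. In the replicate pairs these lists were at -0.72 and -0.42, -0.58 and -0.95, and -0.73 and -0.34. Daughter-cell and M/G1 genes were at -0.65 (adjusted p = 0.000354, and adjusted p = 0.824 with an estimated correlation). The mating-type switching repressor ASH1 (-2.09 ± 0.32), PST1 and the chitinase gene CTS1 (-1.27 ± 0.27) passed with the block. This list was at -0.25 on the replicate 1 and -1.08 on the replicate 2 arrays.

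Anaerobic mannoproteins were lower in the double mutant than in not1-2 by a median of -1.40 (adjusted p = 7e-06, and adjusted p = 0.807 with an estimated correlation). FLO1, DAN1 (-3.12 ± 0.66), PAU7 (-2.81 ± 0.59) and TIR3 (-2.11 ± 0.40) passed with the block, and 7 genes adjusted over the list alone. The list was at -2.18 on the replicate 1 arrays and -0.45 on the replicate 2 arrays. Subtelomeric genes, which also include FLO1, were at -0.94 (adjusted p = 0.00459, and adjusted p = 0.807 with an estimated correlation), with -1.06 and -0.45 in the replicate pairs. Ribosome biogenesis (0.31, adjusted p = 0.000146), purine and one-carbon genes (0.31, adjusted p = 0.0358) and mitochondrial ribosomal proteins (0.18, adjusted p = 0.0411) were higher, at adjusted p = 0.824, 0.875 and 0.875 with an estimated correlation. On the replicate 1 and 2 arrays ribosome biogenesis was at 0.49 and 0.13, purine genes at 0.42 and 0.12 and mitochondrial ribosomal proteins at 0.11 and 0.30. IMD2, for purine synthesis, passed with the block (1.58 ± 0.32), and the mitochondrial call was lost with it, at adjusted p = 0.0568. The block added calls for heat shock genes (0.43, adjusted p = 0.0103), cytosolic ribosomal proteins (0.16, adjusted p = 0.00175) and amino acid synthesis under Gcn4 (0.36, adjusted p = 0.04), all at adjusted p = 0.909 with an estimated correlation, and with it BTN2, a heat shock list member, was at -1.74 ± 0.31. With the ACT1 ratio on top of the block 14 of the 28 named genes called here still passed. The 14 others, SHH3, SPL2, PHO89, PHO5, CTS1, DAN1, PAU7, TIR3, IMD2, SNR41 and BTN2 among them, kept between 92.1% and 109% of their log2 change, at adjusted p of at most 0.0883, in a fit with fewer residual degrees of freedom. The blocked count of 166 was 141 and 139 without a wild-type array, 0 and 10 without not1-2 replicate 1 and 2, 0 and 27 without double-mutant replicate 1 and 2, and 435 and 406 without an spt3 array.

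The double mutant against spt3 shows what not1-2 changes once SPT3 is missing. No probe set passed with limma in either fit, and 10 had an unadjusted p under 0.05, or 46 with the block, of 7043 tested. These are 0.142% and 0.653%, far under the share of 0.05 that no change at all would give. The spread shared by all strains thus did not suit this comparison, and the lack of calls is weak evidence of no change. The called list shifts were those of daughter-cell and M/G1 genes at -0.26, gluconeogenesis genes at -0.21, RNA polymerase I and III subunits at -0.17, purine genes at -0.15 and ribosome biogenesis at -0.14. Their adjusted p was 0.00608, 0.0216, 0.00152, 0.0384 and 0.00354, and adjusted p = 0.875, 0.794, 0.807, 0.875 and 0.865 with an estimated correlation. Of these only ribosome biogenesis stayed below 0 on the replicate 2 arrays, at -0.12; daughter-cell genes were at 0.12, gluconeogenesis genes at 0, RNA polymerase subunits at 0.06 and purine genes at 0.10. With the block the gluconeogenesis call was lost (adjusted p = 0.0595), and cytosolic ribosomal proteins (-0.06, adjusted p = 0.016) and amino acid synthesis under Gcn4 (-0.11, adjusted p = 0.0419) were called, at adjusted p = 0.914 and 0.909 with an estimated correlation; the second list was at -0.36 and 0.11 in the replicate pairs. The replicate pairs of this comparison moved against each other, with r = -0.502 across probe sets. In opposite directions 208 probe sets differed by at least 2-fold, where unrelated pairs would give 21.1. A mean near 0 here averages opposing differences, so it does not show that not1-2 changes nothing without SPT3.

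The probe sets called in not1-2 were then followed in the spt3 background, whose 4 arrays played no part in the estimated change that put them there. The 73 probe sets higher in not1-2 with the block had a median change of 2.27 in the SPT3 background and -0.13 in the spt3 background, and the 67 lower ones had medians of -1.79 and 0.04. The slope of the second change on the first was -0.0527 over all 140, with -0.161 and 0.0558 in the replicate pairs, where equal effects give 1, -0.0541 for 131 probe sets without the a- and alpha-specific lists, and -0.0528 for 127 without the mating-type cassettes and AFB1 as well. The slope over the blocked calls was not planned. None of the 140 passed between the double mutant and spt3. Without the block the called genes were MF(ALPHA)1, MFA2 and HMRA1, whose slope was -0.0942. The not1-2 and wild-type arrays that chose the probe sets inflate the change of 2.27, and leave the value in the spt3 background free of that. Against wild type the 73 had medians of 0.589 in spt3 and 0.468 in the double mutant, and the 67 had -1.04 and -0.75. Part of the change was thus shared by every mutant, and a shared difference lowers the slope without any need for SPT3. Between the double mutant and not1-2 the medians were -1.92 and 0.797. These medians share arrays with the choice.

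**Figure D3:**
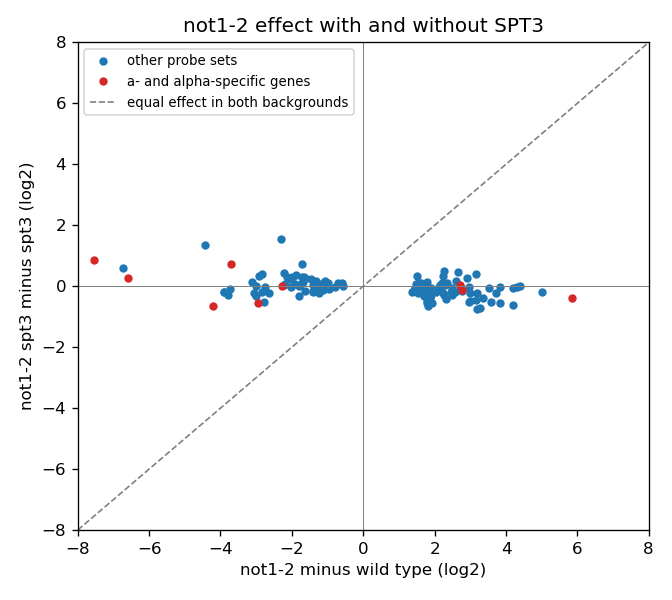
Change with not1-2 in the SPT3 background (horizontal axis, log2) and in the spt3 background (vertical axis, log2) for the 140 probe sets called in not1-2 with the replicate block, with a- and alpha-specific genes in red. The dashed line marks equal effects; the points lie along the horizontal axis, with a slope of -0.0527.

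The interaction tests whether the not1-2 effect differs between the SPT3 and spt3 backgrounds. With the block 6 probe sets passed: CPP3 (-3.94 ± 0.53, adjusted p = 0.0496) and SPG4 (-3.86 ± 0.49, adjusted p = 0.0368), beside MFA2, MFA1, HMRA1 and MF(ALPHA)1. Those mating-type genes differed from wild type the same way in every mutant, so their interaction restates that difference and shows no dependence on SPT3. Only MFA1 and MFA2 passed with quantile normalization on top of the block, where CPP3 and SPG4 were at -4.17 each with adjusted p of 0.0506 and 0.0501, or with the ACT1 ratio, where CPP3 was at -4.10 ± 0.57 (adjusted p = 0.138) and SPG4 at -4.14 ± 0.48 (adjusted p = 0.102) with fewer residual degrees of freedom. With 1 probe set without residual variance left out of the quantile-normalized fit all 6 passed, CPP3 and SPG4 at adjusted p = 0.0467. SPG4 was also at adjusted p = 0.0601 with least-varying probe sets. None passed without the block, where the smallest adjusted p was 0.0631 and 246 probe sets had an unadjusted p under 0.05. The Msn2 and Msn4 targets had an interaction median of -0.81 (adjusted p = 2.04e-07, and adjusted p = 0.575 with an estimated correlation). Cell wall integrity genes had -0.95 (adjusted p = 2.54e-07, and adjusted p = 0.759 with an estimated correlation) and gluconeogenesis genes -0.98 (adjusted p = 0.000291, and adjusted p = 0.759 with an estimated correlation). Phosphate genes had -0.71 (adjusted p = 7.05e-05, and adjusted p = 0.794 with an estimated correlation). The lists of trehalose and glycogen, the respiratory chain, the tricarboxylic acid cycle, peroxisome and daughter-cell genes also passed, with medians between -0.39 and -0.57 and adjusted p between 0.794 and 0.875 with an estimated correlation. By their medians the Msn2 and Msn4, respiratory chain and tricarboxylic acid lists lay above wild type in every mutant. Their interaction therefore holds part of that shared difference. Cell wall integrity genes also lay above wild type in spt3, with a median of 0.24 against 0.85 in not1-2. Between the double mutant and spt3 their median was -0.05. Trehalose and glycogen genes were called as higher than wild type in not1-2 and in the double mutant. The interaction of these lists may thus hold part of a shared difference too. On the replicate 1 and 2 arrays the interaction of daughter-cell genes was at -1.31 and -0.02, peroxisome genes at -1.04 and -0.18, cell wall genes at -1.54 and -0.38, the respiratory chain at -0.69 and -0.25, the tricarboxylic acid list at -0.67 and -0.17 and phosphate genes at -0.31 and -1.52. Without the block HSP12 was at -3.99 ± 0.76, PIR3 at -4.27 ± 0.93, JEN1 at -2.76 ± 0.82 and the phosphate transporter gene PHO84 at -4.49 ± 1.03, none past the test. Cytosolic ribosomal proteins (0.27) were called with the block alone, at adjusted p = 0.000109, and adjusted p = 0.909 with an estimated correlation, and were at 0.51 and 0.14 in the replicate pairs. The blocked count of 6 became 1 without either wild-type array, 3 without not1-2 replicate 1, 0 without not1-2 replicate 2, 3 and 106 without spt3 replicate 1 and 2, and 4 and 2 without a double-mutant array.

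The single mutants shared 7 probe sets higher and 9 lower with the block, where independent lists of these sizes would share 0.124 and 0.266. Of these 16, 7 were a- or alpha-specific genes of the fixed lists, and 11 with the probe sets of the mating-type cassettes, HMRA1 among them, and AFB1 in addition, a set chosen after its values were seen. Without the block they shared MF(ALPHA)1, MFA2 and HMRA1. Both comparisons use the same wild-type arrays. The log2 changes correlated across probe sets with r = 0.487, and unchanged groups simulated against shared controls gave 0.5. The covariance was 0.271 against a simulated 0.0802, at most 0.0912 in 100 simulations. The simulated noise was independent, of the size fitted with the block and alike in every strain. In the data the wild-type replicates differed most, by a median of 0.76 on the log2 scale against 0.467 to 0.558 in the mutants. The simulated covariance may therefore understate what shared controls give. With each single mutant set against a different wild-type array, 1 array per strain and none shared, the covariance was 0.0948 and 0.229 in the 2 ways to split them (r = 0.173 and 0.243), and 0.0537 and 0.176 over the 7026 probe sets outside the wider mating-type set. This split was added after the data were seen and leaves 1 wild-type array to each comparison, and part of the excess may come from the shared controls.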

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

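All tests of explanations in this part were chosen after the results were seen. The results listed first passed the interaction, which sets the effect of not1-2 against its effect in the spt3 strains. A difference of wild type from every mutant alike also gives an interaction. Among the gene lists the interaction median was -0.811 for Msn2 and Msn4 targets, -0.954 for cell wall integrity, -0.983 for gluconeogenesis and glucose-repressed genes and -0.711 for the phosphate regulon. It was -0.419 for trehalose and glycogen metabolism, -0.529 for the respiratory chain, -0.391 for the tricarboxylic acid and glyoxylate cycles, -0.574 for daughter-cell and M/G1 genes and -0.558 for peroxisomal genes. By their medians the Msn2 and Msn4, respiratory chain and tricarboxylic acid lists lay above wild type in every mutant. Their interaction therefore holds part of that shared difference. Cell wall integrity genes also lay above wild type in spt3, with a median of 0.244 against 0.846 in not1-2. Trehalose and glycogen genes were called as higher than wild type in not1-2 and in the double mutant. The interaction of these lists may thus hold part of a shared difference too. The a-specific list had an interaction median of 3.55, and its median against wild type was -4.61 in spt3. With the replicate block the interaction also passed for CPP3 (-3.94) and SPG4 (-3.86), and for the mating-type genes MFA1 (6.85), MFA2 (8.41), HMRA1 (7.35) and MF(ALPHA)1 (-6.25). Those mating-type genes and the a-specific list differed from wild type the same way in every mutant. Their interaction restates that difference and shows no dependence on SPT3. With the ACT1 ratio on top of the block CPP3 (-4.10) and SPG4 (-4.14) were at adjusted p of 0.138 and 0.102. With quantile normalization they were at -4.17 each and at adjusted p of 0.0506 and 0.0501, or 0.0467 each with 1 probe set without residual variance left out.

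The a-specific genes were lower and the alpha-specific genes higher than wild type in all 3 mutants. Shortened RNA on the replicate 1 arrays is argued against as the cause, because on the replicate 2 arrays alone, where the ACT1 ratios lay between 1.79 and 2.10, the list median nearest 0 was -4.11. A wild-type strain of the other mating type than the mutants and an effect of each mutation itself cannot be told apart. All 33 combinations of 11 genes and 3 mutants lay on the side the first predicts in both replicate pairs, but these genes define the pattern, so this restates it. For the second, the a-specific median of -0.761 between the double mutant and not1-2 includes genes at the floor, and no mutant of the other mating type was measured. The alpha-specific genes were above the floor and no higher in the double mutant than in not1-2. Their log2 means were 9.82 against 9.86 for MF(ALPHA)1, 5.35 against 6.25 for MF(ALPHA)2, 6.58 against 6.85 for STE3 and 6.95 against 8.69 for SAG1. Their changes thus did not add up, which alone does not decide between the explanations.

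The replicate 1 arrays stood apart from the replicate 2 arrays in all 4 strains. Scaling of the arrays is argued against, since the lowest of the 6 correlations between deviations was still 0.167 after quantile normalization. Shortened RNA may account for it: the 3' to 5' ratio was higher on replicate 1 in all 12 combinations of 3 control genes and 4 strains. A smaller amount of sample RNA stays open too, with a spike-in signal 1.93 to 2.73 times as high on replicate 1. The 25S ribosomal RNA control differed as well, at 77.2, 134, 374 and 359 on the replicate 1 arrays of wild type, not1-2, spt3 and the double mutant. It was at 2288, 2180, 2380 and 1728 on their replicate 2 arrays. What this difference comes from was not tested. No biological explanation was tested, since the labels give no difference between the replicates.

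Cell wall integrity, phosphate and gluconeogenesis genes were higher in not1-2 than in wild type and lower in the double mutant than in not1-2. Shortened RNA on the replicate 1 arrays stays open as a cause, though the pattern was not confined to them. On the replicate 2 arrays alone all 3 lists had an interaction (-0.38, -1.52 and -0.74) below the 2.5th percentile of 10000 random lists of like size and signal. This cannot decide the question, since the lists had been picked on both pairs and random lists leave out correlation between members. The cell wall interaction was -1.54 on replicate 1. The lower level in the double mutant than in not1-2 was tested with lists chosen on the replicate 1 arrays alone. The test used the replicate 2 arrays of these strains, where no array of the choice and no wild-type array enters. The lower level sets 2 mutant strains against each other and holds no wild-type array by construction. The test therefore could not have pointed to the wild-type arrays as its cause, whatever the outcome. It asked only whether the lower level recurred on arrays outside the choice, and cannot speak on the rise of not1-2 over wild type. Of 41 lists 6 were chosen as higher in not1-2 and lower in the double mutant, these 3 among them, and all 3 lay below the 2.5th percentile of random lists on replicate 2 (-0.339, -0.953 and -0.419), as did all 6. Of the lists not chosen 5 did, so a place below that percentile is not particular to the chosen lists. The rise over wild type may still come from the wild-type arrays, in part or whole. An effect of not1-2 that needs SPT3 stays a hypothesis, since random lists leave out correlation between members, the lowest median between the double mutant and spt3 was -0.206 and that list passed, and no list passed with an estimated correlation.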

How the results depend on the processing

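Settings with the ACT1 ratio as a covariate, and every setting on top of the block, were chosen after seeing the data. Counts are given in the order not1-2, spt3 and double mutant against wild type, double mutant against not1-2, double mutant against spt3, and interaction; without the block they were 3, 4, 5, 2, 0 and 0. They became 1, 2, 7, 3, 0 and 1 with quantile normalization, 3, 4, 3, 2, 0 and 1 without centring and 3, 4, 3, 2, 0 and 0 with least-varying probe sets. They were 2, 2, 2, 2, 0 and 0 without a floor, 3, 5, 7, 2, 0 and 0 with a pseudocount and 1, 4, 2, 0, 0 and 1 without a filter. They were 2, 3, 4, 1, 0 and 0 with the stricter filter, 4, 5, 6, 3, 0 and 0 without the intensity trend, 3, 4, 3, 2, 0 and 0 with all probe sets counted separately, and they did not change when a 2-fold change was asked for in addition. With only the arrays of the strains compared the first 5 counts were 0, 7, 0, 0 and 0, and the interaction cannot be formed. The replicate block gave 140, 40, 14, 166, 0 and 6, and the ACT1 ratio as a covariate 203, 45, 40, 272, 0 and 14. Without each array in turn the counts without the block ran from 0 to 3, 0 to 6, 0 to 3, 0 to 2, 0 to 0 and 0 to 1.

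With the replicate block, quantile normalization gave 105, 13, 13, 168, 0 and 2 calls, no centring 132, 35, 12, 157, 0 and 7, least-varying probe sets 85, 62, 12, 173, 0 and 5, and the ACT1 ratio in addition 74, 2, 6, 84, 0 and 2. Without each array in turn the blocked counts ran from 2 to 306, 5 to 630, 4 to 133, 0 to 435, 0 to 0 and 0 to 106; without wild-type replicate 1, whose ACT1 ratio was highest, they were 4, 5, 4, 141, 0 and 1. Of the 140 blocked calls in not1-2, 3 passed and all 140 had the same sign without wild-type replicate 1. The share of higher calls moved from 30% to 19.4% in spt3 with least-varying probe sets, and from 50% to 100% in the interaction with quantile normalization, which is 2 of 2 calls, and 4 higher and 3 lower once 1 probe set without residual variance is left out. The median of all probe sets in the double mutant against wild type moved from -0.0475 to 0.124 without centring, and in spt3 from -0.0222 to -0.139 with least-varying probe sets.

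The slope of the not1-2 effect in the spt3 background was -0.0942 without the block, -0.0527 with the replicate block (not planned for the slope), -0.105 with quantile normalization and -0.161 to -0.0466 without each array in turn. Of those last 8 settings 4 called no gene and gave no slope. Calls shared by the single mutants numbered 3, 1 with quantile normalization and 16 with the replicate block. The 56 list calls became 0 with an estimated correlation, 58 with quantile normalization, 60 with the replicate block and 51 to 66 without each array in turn. Over the alternatives for the called lists, 480 results kept their side of the threshold, 132 lost it and 4 turned around: cytosolic ribosomal proteins in not1-2 (0.036 with quantile normalization and -0.985 to 0.176 without each array in turn), and, in the double mutant against spt3 without each array in turn, the gluconeogenesis list (-0.42 to 0.0671) and the purine list (-0.421 to 0.147). Over the alternatives for named genes, 1465 kept their side, 154 gained it, 115 lost it and none changed sign. The cause of these changes was tested only for probe sets without residual variance, below. The filter on probe sets of another species was not run. Signal over background sets the limit for genes near the floor of 1.72, which have no order there.

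Probe sets with no residual variance were left out in a run added after seeing the results. The main and blocked fits had none, quantile normalization had 1, 5 of the 8 settings without an array had 1 to 4, and no filter had 139. Without the block, leaving them out gave 1, 4, 2, 2, 0 and 0 calls with no filter, changed nothing with quantile normalization or without spt3 replicate 2, and gave 4, 6, 4, 13, 0 and 1 without wild-type replicate 2, 2, 4, 3, 0, 0 and 0 without not1-2 replicate 1, 0, 5, 3, 0, 0 and 0 without not1-2 replicate 2, and 2, 6, 0, 0, 0 and 0 without double-mutant replicate 2. With the block it gave 107, 13, 13, 170, 0 and 7 with quantile normalization. With the block and no filter the counts were 1, 2, 1, 0, 0 and 0 with these probe sets and 43, 10, 10, 36, 0 and 2 without them. With the block they became 11, 15, 12, 205, 0 and 2 without wild-type replicate 2, 3, 10, 9, 0, 0 and 3 without not1-2 replicate 1, 3, 10, 11, 20, 0 and 2 without not1-2 replicate 2, 309, 690, 159, 436, 0 and 115 without spt3 replicate 2, and 86, 20, 9, 28, 0 and 2 without double-mutant replicate 2. These counts still depend on single arrays.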

Other observations

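All values in this part were looked at after the data were seen, and none was tested as a class. Probe sets for tRNA genes lay lower in not1-2 than in wild type: of 90, 4 lay above, with a median of -1.58, and -1.65 and -1.39 in the replicate pairs, and 12 passed with the replicate block. In spt3 their median was -1.07, but -1.95 on the replicate 1 and -0.13 on the replicate 2 arrays, and in the double mutant -0.96, with -0.51 and -1.36. Mitochondrially encoded protein genes had a median of -1.67 in not1-2 over 7 probe sets, with -1.55 on the replicate 1 and -0.69 on the replicate 2 arrays; 2 lay above wild type and 2 passed with the block, COB among them, and medians of -0.66 in spt3 and -0.73 in the double mutant. The medians of both classes thus lay below wild type in all 3 mutants. Both directions held in not1-2 under the 3 other scalings. The labelled RNA was polyA RNA per the labels, while the 25S ribosomal RNA control ran from 77.2 to 2380 across the arrays. Whether the signals of these classes follow transcript level or the share of RNA without a polyA tail was not tested.

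Family probe sets without a single gene name, which match several related sequences, followed spt3 in both backgrounds. Over 335 of them the median was -0.94 in spt3 against wild type and -1.11 in the double mutant against not1-2, comparisons that share no array, and 0.13 in not1-2 against wild type and -0.03 in the double mutant against spt3, the last of which turned to between 0.01 and 0.03 under the other scalings. In the replicate pairs the first was -1.41 and -0.51, and the second -0.99 and -1.11. With the block 10 and 39 of them passed as lower in the first pair of comparisons. Related sequences share signal, so these probe sets are not independent, and their genes are not named here. The other 1353 probe sets without a single gene name had medians of -0.55 and -0.11 in the same pair of comparisons.

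The complexes that hold the mutated proteins showed no called shift in any of the 6 comparisons: over them the list median ran from -0.088 to 0.34 for the Ccr4-Not complex and from -0.14 to 0.30 for SAGA. Glycolytic genes ran from -0.35 to 0.37 and ergosterol genes from -0.25 to 0.28, also with no call.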
